A study of Mus musculus with 4 samples.

How the data were processed

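Cerebellum RNA of mice at postnatal day 30 was compared between Dicer mutants (mGfap-Cre with both Dicer alleles floxed) and littermate controls (mGfap-Cre with 1 floxed allele), per the labels. The labels give 4 biologically independent littermate pairs of mixed strain background. Each pair shared 1 array of a 2-colour Agilent whole mouse genome design. The mutant was in Cy5 for replicates 1 and 3 and in Cy3 for replicates 2 and 4, so genotype and dye were balanced. Each channel was made from 500 ng of total RNA by linear amplification, per the labels. All 4 arrays were on 1 slide and shared a scan, so no slide or scan batch could be formed, and dye was the technical factor in the design.

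The deposited array files hold linear spot and local background intensities of both dyes, read by Agilent Feature Extraction 10.5.1.1 with no further normalization, per the file headers. The same deposited files hold processed intensities, which the software had background-subtracted, detrended over the array and normalized between dyes with a linear and a LOWESS step. They also hold a log10 ratio of Cy5 over Cy3 made by the authors' scanner software from those processed intensities. The deposited value table of the series holds the same log10 ratios with the sign turned for replicates 2 and 4, which makes them mutant over control. This was checked spot by spot and the largest difference was 4.84e-06. Quality flags of the software (well above background, saturation, non-uniformity and population outliers) were used as deposited. Probe coordinates refer to mouse genome build mm9, per the file headers.

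Values were recomputed from the mean spot intensities and median local backgrounds with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8), jsonlite 2.0.0 and statmod 1.5.0. Background was corrected with normexp and an offset of 50. Ratios of Cy5 to Cy3 were normalized by loess within each array, with control spots and spots with an outlier flag at weight 0, and no scaling between arrays. Spots with an outlier flag in either channel were set missing, and spots of 1 probe were averaged. The array held 45018 spots, of which 43379 were not controls, and 41174 different probes. The symbol came from the transcript accession through the current reference table for 24844 probes and from the array file for the other 16330, which gave 28632 names. A probe was tested if it was well above background in the mutant channel of all 4 arrays or in the control channel of all 4, and had a value on at least 3 arrays with both dye orders present. The probe with the highest mean brightness stood for a gene. This left 18025 genes, of which 28 lacked a value on 1 array. Between 143 and 248 spots per array carried an outlier flag, and no spot was saturated.

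The order of the normexp step and the flags was chosen after the data and a first set of counts had been seen. On the array of replicate 1, a speck over 2 spots (App and 4921511H03Rik) raised the local Cy3 background to 145269 and 81260.5. With all spots in the normexp fit, its estimated mean for that array was -730 in Cy3 and -241 in Cy5. Without the spots that carried an outlier flag it was 8.62 and -9.40, while the other arrays lay between 9.66 and 12.4 in Cy3 and between -11.6 and -7.06 in Cy5. Those spots were therefore left out of the normexp fit. The order used first, with the flags after normexp, gave 50 genes higher and 32 lower in place of 106 and 80, and was kept as an alternative.

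Genes were tested with limma on log2(Cy5/Cy3), with a dye term and a genotype term whose sign followed the mutant's dye, moderated variances and Benjamini-Hochberg adjustment over the 18025 genes. A gene was called at an adjusted p under 0.05. There were 2 residual degrees of freedom and 3.37 prior degrees of freedom. Because mutant and control shared an array, each ratio was a paired comparison. The pairing was checked across genes on channel intensities normalized between arrays, with mean, dye and genotype fitted out. The channels of 1 array correlated at 0.395 to 0.704, and channels of different arrays at no more than 0.231. Both channels are read from the same spots, so this holds shared spot effects and does not measure littermates alone. Errors are SDs of the log2 ratio over the 4 pairs. A fold for a gene whose control or mutant channel was above background on no array was computed as a lower bound against the dimmest level called well above background.

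Before the data were examined, 31 gene lists, the tests, most of the alternatives and the rule for named genes had been written down. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over lists, and needed at least 5 tested members. The alternatives to it were camera with a correlation estimated for each list, and fry. The list of brainstem and midbrain genes was not tested, because 4 of its 16 genes passed the filter; their median log2 ratio was -0.04. Named genes were Dicer1, the 12 called genes with the largest and the 12 with the smallest log2 ratio and 1 sign in all 4 pairs (leaving out accessions, clone names and predicted genes), and up to 4 called members of each list by size, or the 2 members with the smallest p where none was called. Genes named outside that rule are said to be so, and 2 genes that the rule names are not reported here.

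Alternatives covered the background correction, the software's processed intensities, median spot values, median centring, scaling between arrays, the filter on dim probes, the dye term, the pairing, the variance model, array weights, the probe that stands for a gene, the series value table, a 1.5-fold threshold and leaving out each replicate in turn. A test of microRNA seed matches in 3 prime untranslated regions, and its 8-base version, had also been set down but was not run, because the reference used here holds no such sequences. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

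The procedure was tested on simulated ratios with the design, brightness and noise of these arrays, with independent noise between genes. Of 50 genes changed at each size, it called 24% at a log2 ratio of 0.5, 72% at 0.75, 80% at 1 and 100% at 2. Of 150 genes called in the simulation, 9 (6%) had not been changed. A list shifted by 0.4 reached an adjusted p of 5.81e-26 with the preset correlation and 0.251 with an estimated one. Precision was limited by the number of arrays.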

Results

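Transcript levels in the cerebellum of 30-day-old mice were measured on 4 two-colour arrays. Each array carried 1 Dicer mutant and its control littermate, so 4 mutant and 4 control animals were compared as 4 pairs. In the mutants, a Cre recombinase under a mouse Gfap promoter acted on 2 floxed alleles of Dicer, the gene of the enzyme that makes mature microRNAs. Controls carried the same Cre and 1 floxed allele. Between 26398 and 28907 probes per array were well above background in the mutant channel and between 26291 and 27718 in the control channel, of 41174 probes. The number of arrays limits the precision of every value. Ratios are mutant over control on the log2 scale, given as mean ± SD over the pairs (n = 4 unless stated), and adjusted p values are from limma over 18025 genes.

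The comparison asks how the cerebellum responds when Dicer is deleted in astroglia, and the series title places the question on neurons as well. Dicer1 itself did not differ detectably in whole tissue, with a log2 ratio of 0.04 ± 0.22 and an adjusted p of 0.947 (probe A_51_P483059, chromosome 12, 105960373 to 105960432, build mm9). Its other probe gave -0.06 ± 0.18 (A_51_P333060, chromosome 12, 105930664 to 105932735). The position of both probes relative to the floxed part of the gene was not established, and astroglia are a part of the tissue only, so these values do not measure the deletion.

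Of 18025 genes, 106 were higher and 80 were lower in mutant cerebellum, and each of these 186 genes had the same direction in all 4 pairs. The called log2 ratios ran from 0.47 to 3.84 for higher genes (median 0.87) and from -1.68 to -0.44 for lower genes (median -0.73), against a median of 0.00 over all genes and a median SD between pairs of 0.16. At least 2-fold differences were seen for 36 of the higher and 15 of the lower genes. The counts were 50 and 32 when the outlier flags were applied after the background fit, an order replaced after the data had been seen, and 16 of the 39 named genes that were called did not pass then, among them Slc10a4 (adjusted p = 0.0517) and Cxcl10 (adjusted p = 0.0580). They were 44 and 13 without replicate 1, 140 and 127 without replicate 2, 60 and 31 without replicate 3, and 215 and 121 without replicate 4, and the processed signals of the scanner software gave 88 and 53, where Ntsr2, Cldn10, Ccnd1, Slc1a2 and Itgb1 among the named genes did not pass.

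The gene with the largest ratio was Slc10a4, a vesicular transporter-like protein of cholinergic and monoaminergic neurons, at 3.84 ± 0.24 (14.3-fold, adjusted p = 0.000403, probe A_51_P448479, chromosome 5, 73404101 to 73404160). The control channel of this probe was above background in 3 of 4 arrays, and the ratio of Slc10a4 ran from 2.79 to 5.47 over the alternatives, so its size is uncertain. The interferon-inducible chemokine gene Cxcl10 rose by 2.57 ± 0.38, and its control channel was above background in 2 of 4 arrays. P4ha2 (2.43 ± 0.21) and Plod2 (1.56 ± 0.22), enzymes that hydroxylate collagen, both rose. So did the matrix glycoprotein Tnc (2.19 ± 0.27), the basement membrane protein Frem2 (2.01 ± 0.13) and the matrix protein Fbln1 (1.62 ± 0.28). Greb1l rose by 2.05 ± 0.29, the nephrin-like adhesion protein Kirrel2 by 1.91 ± 0.39, the ferric reductase Cybrd1 by 1.90 ± 0.40 and the vitamin E carrier Ttpa by 1.76 ± 0.15. The further probes of Slc10a4, Tnc, Kirrel2 and Frem2 had the same sign, at 0.96 for Frem2 and 0.64 for 1 of the 2 of Tnc. The control channel was above background on 0 of 4 arrays for the other Tnc probe and for that of Slc10a4, and on 1 of 4 for that of Kirrel2, so the size of the difference was not measured there. With the mean over probes, which includes these, Tnc stood at 1.23 and Kirrel2 at 1.24, both still called. Cxcl10 stood at 4.66 with the processed signals. With the flags after the background fit, Frem2 (adjusted p = 0.0718), Cybrd1 (adjusted p = 0.0865) and Plod2 (adjusted p = 0.0570) did not pass.

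Among lower genes, Dhrs2, a short-chain dehydrogenase, had the smallest ratio at -1.68 ± 0.21 (adjusted p = 0.00431, probe A_51_P174215, chromosome 14, 55860173 to 55860232), and -2.76 with the processed signals. The signalling adaptor Traf1 (-1.62 ± 0.35), the neuropeptide gene Npy (-1.60 ± 0.37) and Dao, the D-amino acid oxidase of cerebellar astroglia (-1.39 ± 0.23), were also lower. Fam107a (-1.35 ± 0.26), the deaminase Rida (-1.29 ± 0.11), Baalc (-1.26 ± 0.27) and the secreted proteins Lgi4 (-1.19 ± 0.32) and Metrn (-1.11 ± 0.33) followed. Rlbp1, which binds retinaldehyde, stood at -1.10 ± 0.09, the calcium-binding S100a6 at -1.03 ± 0.21 and Eva1a at -1.02 ± 0.20. Lgi4 (adjusted p = 0.0554), Metrn (adjusted p = 0.0555) and S100a6 (adjusted p = 0.0541) did not pass without replicate 1. With the flags after the background fit, Dhrs2 (-1.24, adjusted p = 0.107), Dao (adjusted p = 0.0630), Baalc (adjusted p = 0.0754), Rlbp1 (adjusted p = 0.116) and Eva1a (adjusted p = 0.0549) did not pass.

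**Figure D1:**
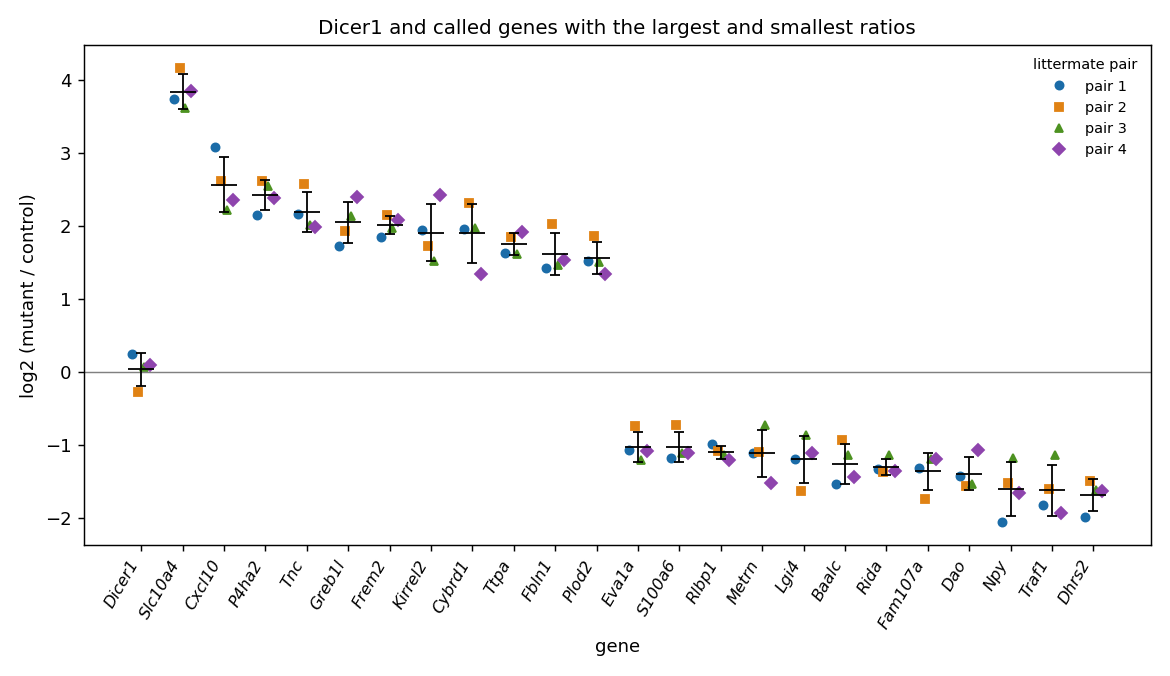
Log2 ratio of mutant over control (vertical axis) for Dicer1 and for 11 of the 12 called genes with the largest ratio and the 12 with the smallest, 1 symbol per littermate pair, with the mean (long line) and SD (short lines) over 4 pairs. The pairs lie on 1 side of 0 for each gene but Dicer1, whose mean is 0.04.

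Genes of mature astroglia moved both ways. Of 40 tested members of that list, 2 rose and 8 fell (7 and 15 adjusted over the list alone), and the other 30 did not pass. Aldh1l1, a folate enzyme widely used as an astrocyte marker, rose by 1.5 ± 0.23 and the urea transporter Slc14a1 by 0.98 ± 0.23. The neurotensin receptor Ntsr2 (-1.01 ± 0.26), the claudin Cldn10 (-1.0 ± 0.49), the thyroid hormone-activating enzyme Dio2 (-0.89 ± 0.14), Clu (-0.77 ± 0.17), Plpp3 (-0.70 ± 0.20), the glutamate transporter Slc1a2 (-0.57 ± 0.11), S100b (-0.56 ± 0.09) and the water channel Aqp4 (-0.54 ± 0.26) fell; the names of Dio2, Clu, Plpp3, S100b and Aqp4 were added after their values were seen, to complete the count. The list as a whole had a median of -0.19 and was called lower (adjusted p = 2.00e-05), with adjusted p = 0.286 with an estimated correlation, and its median was -0.12 without replicate 4. Without replicate 1, Ntsr2 (adjusted p = 0.105), Cldn10 (adjusted p = 0.0748), Slc14a1 (adjusted p = 0.0554) and Slc1a2 (adjusted p = 0.181) did not pass, and without replicate 3 Ntsr2 (adjusted p = 0.0886) and Slc1a2 (adjusted p = 0.165) did not. Slc1a2 also did not pass with the mean over its 3 probes (-0.37, adjusted p = 0.183), with the flags after the background fit (-0.46, adjusted p = 0.178), with median centring (adjusted p = 0.0914) or with no replicate block (adjusted p = 0.0520). Cldn10 missed the threshold in several other settings, for instance without background subtraction (adjusted p = 0.0514).

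Of 21 tested genes of immature or progenitor glia, 4 rose and none fell (9 and 0 adjusted over the list alone). Tnc had the largest ratio, and the brain lipid-binding protein gene Fabp7 rose by 1.06 ± 0.51, the intermediate filament gene Vim by 0.92 ± 0.08 and Thbs2, a secreted thrombospondin, by 0.60 ± 0.06. The list median was 0.16 and the list was called higher (adjusted p = 2.42e-08), with adjusted p = 0.286 with an estimated correlation. Its median was 0.25 without replicate 1, 0.24 without replicate 4 and 0.24 with the processed signals or the value table of the series. Bergmann glia, the radial astroglia of the cerebellar cortex, were not called as a list (adjusted p = 0.433). Of 18 members, Tnc, Fabp7 and Vim rose, while Dao, Dbi (-0.77 ± 0.22) and the glutamate receptor subunit Gria4 (-0.44 ± 0.33) fell (6 and 6 adjusted over the list alone). Dbi and Gria4 were named after their values were seen. The median (-0.10) and the mean (0.06) of that list differed in sign. Without replicate 1, Thbs2 did not pass (adjusted p = 0.138), and without replicate 3 Thbs2 (adjusted p = 0.115) and Fabp7 (adjusted p = 0.0589) did not. Thbs2 also did not pass with the flags after the background fit (0.46, adjusted p = 0.224), nor Fabp7 with no replicate block (adjusted p = 0.0870).

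**Figure D2:**
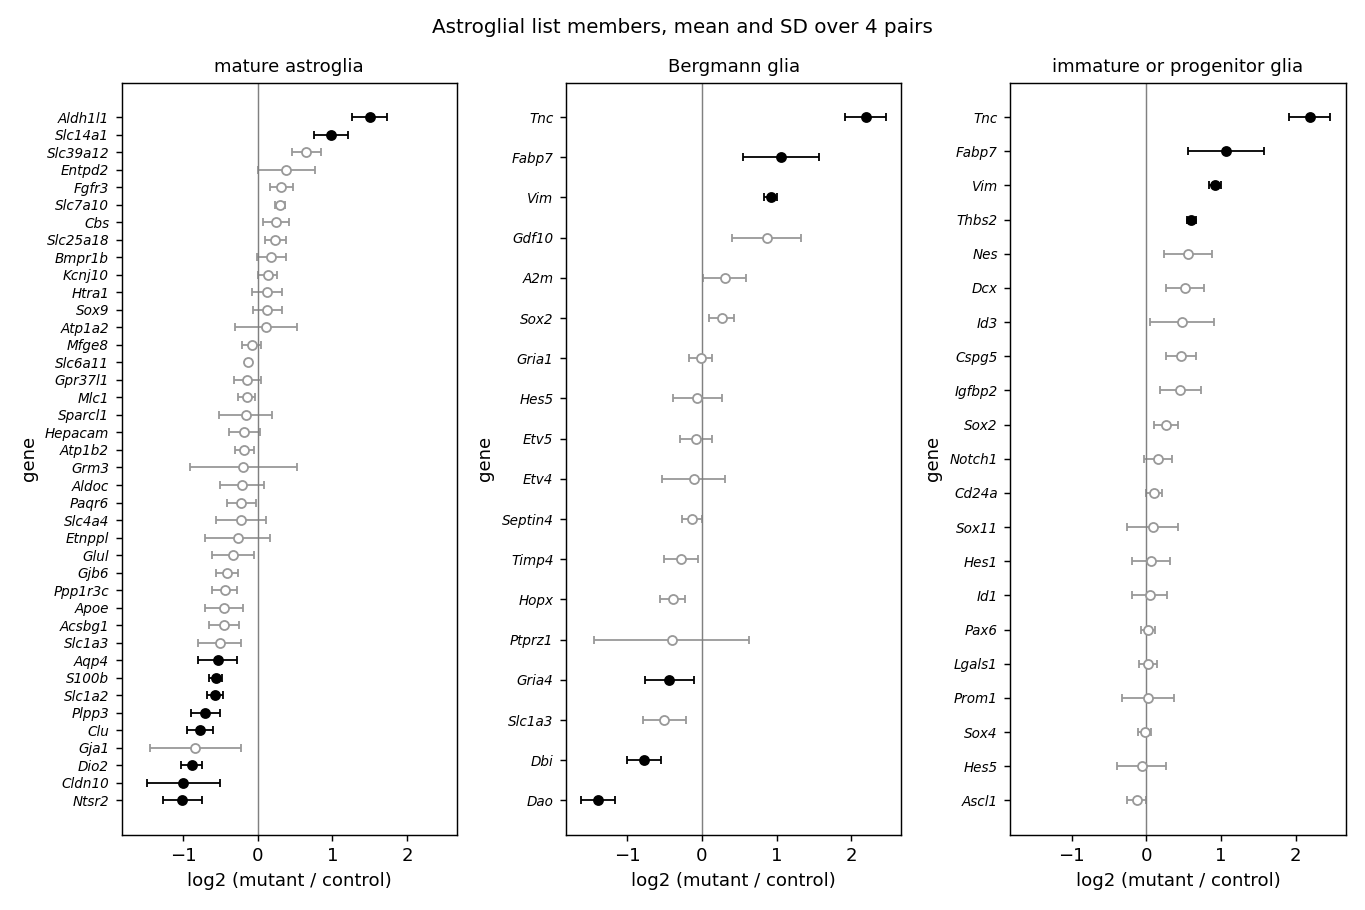
Mean log2 ratio of mutant over control (horizontal axis) for each tested member of 3 astroglial gene lists, with bars for the SD over 4 pairs; filled points passed an adjusted p of 0.05. Mature astroglial genes lie on both sides of 0, from -1.01 to 1.5, and the 4 called genes of immature glia lie between 0.60 and 2.19.

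Markers of reactive astroglia were mixed. Of 11 tested genes that rise in astroglia after many kinds of injury, 4 rose and none fell (5 and 2 adjusted over the list alone). They were Cxcl10, the intermediate filament gene Gfap (1.47 ± 0.35), the ferroxidase gene Cp (1.21 ± 0.22) and Vim. The further probes of Gfap gave 0.75 and 0.91. That list was called higher with a median of 0.04 (adjusted p = 0.0209), with adjusted p = 0.518 with an estimated correlation. It was not called without replicate 4 (median 0.14, adjusted p = 0.0584), its median was 0.01 without replicate 1, 0.07 without replicate 3, 0.01 with the median signals and 0.02 with median centring, and with the stricter filter on dim probes, which leaves out Cxcl10, its median was -0.01 (adjusted p = 0.159). Over all alternatives its median ran from -0.04 to 0.14. Of 12 genes induced in astroglia by lipopolysaccharide, Amigo2 rose (1.07 ± 0.14) and the others did not pass (1 higher and 0 lower adjusted over the list alone); Amigo2 did not pass with the flags after the background fit (0.88, adjusted p = 0.0715). Of 9 genes induced in astroglia by ischemia, S100a10 fell (-0.99 ± 0.15) and none rose (1 and 1 adjusted over the list alone). Neither of these lists was called (adjusted p = 0.110 and 0.958), but the lipopolysaccharide list was called higher without replicate 3 (median 0.11, adjusted p = 0.00107). The median of the ischemia list (0.04) and its mean (-0.05) differed in sign.

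No gene of the neuronal lists passed the test, also adjusted over the list alone. The lists held 24 tested genes of Purkinje neurons (median -0.01), 22 of granule neurons (0.01) and 14 of GABAergic interneurons (-0.01), and none of these lists was called (adjusted p = 0.680, 0.758 and 0.514). For granule neurons the median differed in sign from the mean (-0.01). Among the members with the smallest p were Itpr1 (0.14 ± 0.29) for Purkinje neurons, Slc17a7 (-0.19 ± 0.21) and Zic1 (0.18 ± 0.39) for granule neurons, and Gad1 (-0.09 ± 0.11) and Prkcd (-0.09 ± 0.16) for interneurons. Of 29 tested genes of synaptic vesicles and the postsynaptic density none passed, also adjusted over the list alone, with Vamp2 at -0.23 ± 0.23 and Dlg4 at -0.16 ± 0.05. That list was called lower with a median of -0.05 (adjusted p = 0.0192), with adjusted p = 0.518 with an estimated correlation. It was not called without replicate 2 (-0.03, adjusted p = 0.0637), replicate 3 (-0.03, adjusted p = 0.200) or replicate 4 (-0.08, adjusted p = 0.0664), nor with median centring (-0.05, adjusted p = 0.0509), and its median was -0.07 without replicate 1. On simulated ratios, 24% of changes of 0.5 were called, so differences of the size measured in neuronal genes were mostly not detectable with 4 pairs. Of 19 genes of glutamate and GABA uptake and turnover, Slc1a2 fell (0 higher and 2 lower adjusted over the list alone) and the list was not called (adjusted p = 0.156).

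Microglial genes showed no called change. Of 25 tested microglia genes (median 0.03) and 13 genes of activated microglia (0.05) none passed, with Gpr34 at 0.16 ± 0.07, Selplg at -0.17 ± 0.21, Cd9 at -0.41 ± 0.32 and Ch25h at -0.22 ± 0.28. Neither list was called (adjusted p = 0.558 and 0.993), and for activated microglia the mean (-0.01) differed in sign from the median. The microglia list was called higher without replicate 4 (0.09, adjusted p = 0.0274), and Cd9 passed without replicate 2 (-0.60, adjusted p = 0.0226). That list call used the preset correlation of 0.01, while the one estimated for microglia with all 4 pairs was 0.467. Of 21 interferon response genes none passed and the list was not called (adjusted p = 0.0563), with Ifi27l2a at 0.37 ± 0.16 and Bst2 at 0.23 ± 0.06. It was called higher without replicate 3 (0.13, adjusted p = 0.00213) and without replicate 4 (0.13, adjusted p = 0.00744), and in 4 other settings: without background subtraction (0.07, adjusted p = 0.0371), with no filter on dim probes (0.07, adjusted p = 0.0213), and with the processed signals or the value table of the series (0.11, adjusted p = 0.0383 in both). Of 9 genes of MHC class I presentation none passed (adjusted p = 0.111 for the list), with Tapbp at 0.20 ± 0.13 and Psmb9 at 0.13 ± 0.11, and the list was called higher without replicate 3 (0.15, adjusted p = 0.00680) and with no filter on dim probes (0.10, adjusted p = 0.0368). None of the genes of these 4 lists passed when adjusted over the list alone.

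Genes of oligodendrocytes and myelin were called lower as a list, with a median of -0.23 over 20 tested genes (adjusted p = 2.31e-07) but adjusted p = 0.514 with an estimated correlation. None of them passed the test, also adjusted over the list alone, and 19 of 20 ratios were below 0. Opalin stood at -0.40 ± 0.20, and passed without replicate 2 (-0.52, adjusted p = 0.0324), and the myelin claudin gene Cldn11 at -0.34 ± 0.17. The list median was -0.12 without replicate 3. Of 10 oligodendrocyte precursor genes none passed, also adjusted over the list alone, and the list was not called (adjusted p = 0.168), with Vcan at 0.36 ± 0.18 and Bmp4 at -0.13 ± 0.12. Of 22 cholesterol synthesis genes, none passed over all genes and 7 were lower adjusted over the list alone, with Mvk at -0.39 ± 0.16 and Cyp51 at -0.35 ± 0.06. Their median was -0.16 and the list was called lower (adjusted p = 5.91e-08), with adjusted p = 0.286 with an estimated correlation. Of 22 oxidative stress and heat shock genes, none passed over all genes and 6 were lower adjusted over the list alone, with the metallothioneins Mt1 at -0.52 ± 0.14 and Mt2 at -0.57 ± 0.28. That list was called lower (median -0.10, adjusted p = 3.03e-05), with adjusted p = 0.286 with an estimated correlation. Mt1 passed without replicate 4 (-0.60, adjusted p = 0.0242), with no dye term (adjusted p = 0.0209) and with an intensity trend and robust variances (adjusted p = 0.0469), and Mt2 without replicate 2 (-0.66, adjusted p = 0.0482).

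Of 25 cell cycle genes, the cyclin D1 gene Ccnd1 rose (0.98 ± 0.24) and 7 were higher adjusted over the list alone, while 24 of 25 ratios were above 0. The list median was 0.21 and the list was called higher (adjusted p = 1.26e-08), with adjusted p = 0.512 with an estimated correlation, and its median was 0.32 with the processed signals or the value table of the series. Ccnd1 did not pass without replicate 1 (0.84, adjusted p = 0.0541) or with median centring (0.97, adjusted p = 0.0601). Of 20 p53 target and cell death genes, the receptor gene Eda2r rose (3 were higher adjusted over the list alone). Eda2r was above background in the control channel of 0 of 4 arrays, so it was at least 1.55-fold higher; its adjusted p was 0.136 without replicate 1, 0.0948 without replicate 3 and 0.130 with the flags after the background fit. The p53 list was called higher (median 0.07, adjusted p = 0.00350), with adjusted p = 0.514 with an estimated correlation, and not without replicate 2 (0.01, adjusted p = 0.109). Of 11 genes of insulin-like growth factor signalling none passed and 3 were higher adjusted over the list alone, with Igfbp2 at 0.45 ± 0.28 (0.62 without replicate 2, adjusted p = 0.0244) and Igfbp4 at 0.32 ± 0.19. That list was called higher (median 0.04, adjusted p = 0.0240), with adjusted p = 0.514 with an estimated correlation, but not without replicate 1 (0.05, adjusted p = 0.192) or replicate 2 (0.10, adjusted p = 0.0644), and its median was 0.17 without replicate 3 and 0.11 without replicate 4. Its median was 0.0020 with the mean over probes and 0.084 with the flags after the background fit, still called in both (adjusted p = 0.0459 and 0.0151). Of 21 targets of the let-7 microRNAs and heterochronic genes, Ccnd1 rose (2 were higher adjusted over the list alone), and the list was not called (adjusted p = 0.10), except without replicate 1 (0.08, adjusted p = 0.0334) and with no filter on dim probes (0.05, adjusted p = 0.0368). Of 14 genes of the microRNA machinery none passed, also adjusted over the list alone, and the list was not called (adjusted p = 0.173), with Tnrc6a at 0.24 ± 0.12 and Ago3 at -0.11 ± 0.14.

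Of 29 genes of extracellular matrix and adhesion, Tnc and the integrin gene Itgb1 (0.49 ± 0.09) rose (7 higher and 1 lower adjusted over the list alone). The list was called higher (median 0.15, adjusted p = 0.00213), with adjusted p = 0.518 with an estimated correlation, but not without replicate 1 (0.05, adjusted p = 0.113), and its median was 0.09 without replicate 2 and 0.10 with the flags after the background fit. Itgb1 did not pass without replicate 1 (adjusted p = 0.310), replicate 3 (adjusted p = 0.208) or replicate 4 (adjusted p = 0.0513), nor with median centring (adjusted p = 0.178), no replicate block (adjusted p = 0.0691), the mean over probes (0.37, adjusted p = 0.0574) or the flags after the background fit (adjusted p = 0.0668). Of 14 genes of meninges and fibroblasts, a tissue that lies on the cerebellum, none passed and 3 were higher adjusted over the list alone, with Lum at 0.56 ± 0.36 and Dcn at 0.52 ± 0.30. That list was called higher as well (median 0.12, adjusted p = 0.00187), with adjusted p = 0.512 with an estimated correlation. Of 16 endothelial genes none passed, also adjusted over the list alone, with Vwf at -0.27 ± 0.39 and Slc16a1 at 0.25 ± 0.29. The endothelial list was called lower (median -0.08, adjusted p = 0.0188), with adjusted p = 0.607 with an estimated correlation, but not without replicate 3 (-0.04, adjusted p = 0.722) or replicate 4 (-0.10, adjusted p = 0.105), and its median was -0.17 without replicate 1.

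Lists of tissue that can be carried along at dissection varied between pairs. The medians of 13 choroid plexus genes in pairs 1 to 4 were 0.08, -0.58, 0.38 and 0.55, and the list was not called (adjusted p = 0.219), with Otx2 at 0.08 ± 0.20 and Enpp2 at 0.15 ± 0.46. It was called higher without replicate 1 (0.18, adjusted p = 0.0317) and without replicate 2 (0.39, adjusted p = 2.29e-11), and lower without replicate 4 (-0.17, adjusted p = 0.00136). The 6 blood cell genes had pair medians of 0.49, -0.62, 0.18 and -0.11 (adjusted p = 0.818), and were called higher without replicate 2 (0.22, adjusted p = 0.0232), with Eraf at 0.24 ± 0.74 and Alas2 at -0.14 ± 0.28. Of 17 immediate early genes none passed (adjusted p = 0.153 for the list), with Dusp1 at -0.54 ± 0.49 and Dusp6 at 0.36 ± 0.29. That list was called lower without replicate 1 (-0.13, adjusted p = 0.000226), and Dusp6 passed without replicate 4 (0.47, adjusted p = 0.0431). The estimated correlation with all 4 pairs was 0.965 for choroid plexus genes, so these moved almost as 1 value. It was 0.377 for immediate early genes and 0.429 for blood cell genes, also above the preset one. No gene of these 3 lists passed adjusted over the list alone.

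In all, 30 lists were tested, of which 7 were called higher and 6 lower with the preset correlation. With a correlation estimated for each list none was called, and 4 had an unadjusted p under 0.05. In the simulation this version also missed a list shifted by 0.4 (adjusted p = 0.251), so its lack of calls cannot decide for or against a list. The estimated correlation lay below the preset 0.01 for immature or progenitor glia (-0.045), cholesterol synthesis (-0.006), mature astroglia (-0.016) and oxidative stress (-0.024). For all other called lists, oligodendrocytes and myelin and cell cycle among them, it lay above the preset value. It ran there from 0.0527 for meninges and fibroblasts to 0.383 for endothelium. The small adjusted p values of those lists thus rest on a preset correlation lower than the one estimated. The preset correlation also called 8 and 4 lists in the swapped assignments with balanced dyes, where genotype cancels out of the contrast. Its adjusted p values are thus not calibrated. By fry, which asks whether the genes of a list move on balance in 1 direction and makes no comparison with other genes, immature or progenitor glia (higher), mature astroglia (lower) and oxidative stress and heat shock (lower) were called, each with an adjusted p of 0.0246. By its mixed version, which counts change in either direction, 14 lists were called. Some of them were not called by camera: Bergmann glia (adjusted p = 0.00946) and reactive astroglia after lipopolysaccharide (0.0145) and after ischemia (0.0200). The others were glutamate and GABA uptake and turnover (0.0145), let-7 and heterochronic targets (0.0176) and oligodendrocyte precursors (0.0215). The lists share members: Tnc is in 3 of them. The dye effect passed for 0 genes in limma, with 1621 at an unadjusted p under 0.05.

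**Figure D3:**
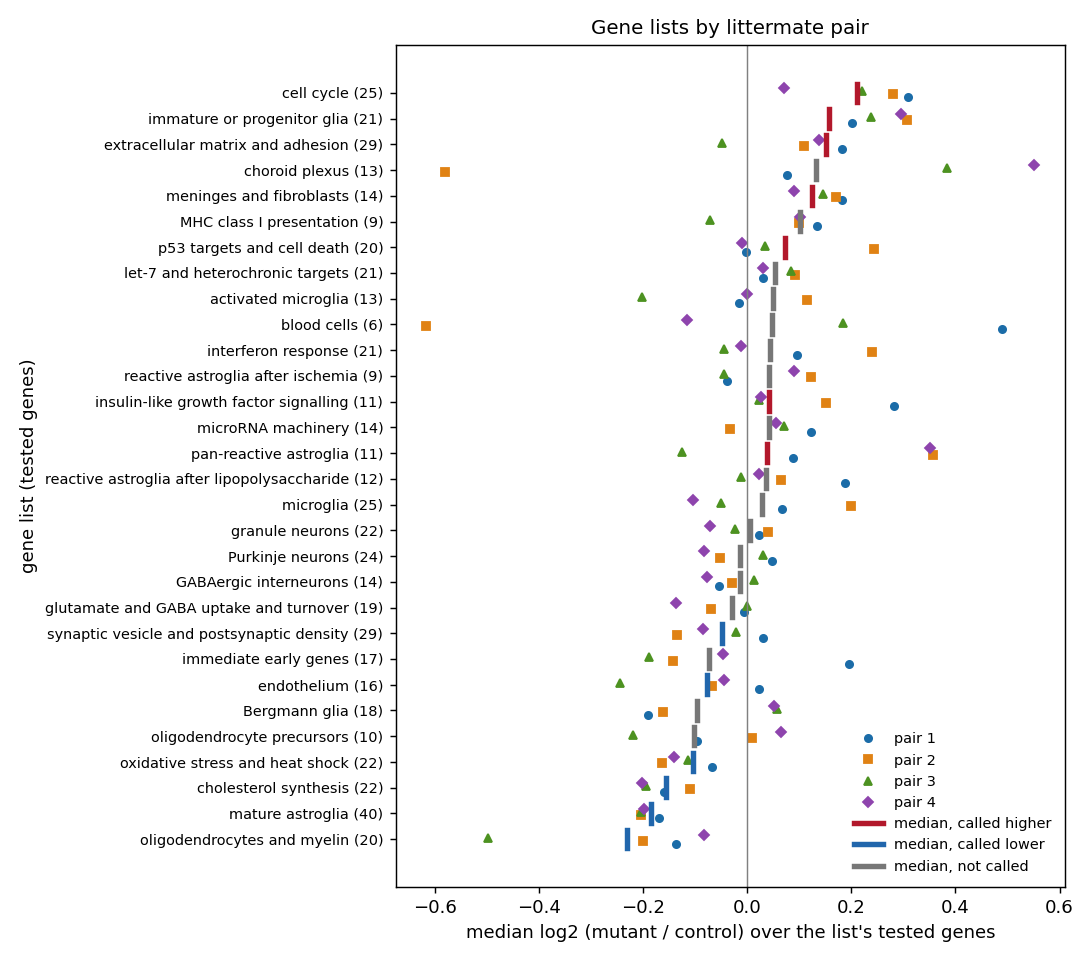
Median log2 ratio of mutant over control over the tested genes of each of 30 gene lists (horizontal axis), 1 symbol per littermate pair, with a bar at the median of the fitted ratios coloured by the call of camera at the preset correlation; tested genes are in brackets. Mature astroglia lie at -0.19 with the pairs between -0.20 and -0.17, while choroid plexus pairs run from -0.58 to 0.55.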

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

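The counts of other splits for genes, and the 4 tests on mature astroglial genes, were chosen after the results they measure had been seen; the tests on pair 1 and on genes with opposite ratios, and the count of splits for lists, were set down before. Whether 1 pair stood apart from the other 3 was tested for 78 named genes and 30 list medians, and 11 of these 108 did at the 95% level of Dixon's test for 4 values, against 5.4 by chance. They fell on all 4 replicates (3, 2, 4 and 2 on replicates 1 to 4).

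Replicate 1 stood apart for Lum (1.09, others 0.33 to 0.46), for Eraf (1.34, others -0.19 to -0.05) and for the median of the mature astroglia list (-0.17, others -0.20). Replicate 2 did so for S100a6 (-0.72, others -1.17 to -1.10) and for the median of the p53 target and cell death list (0.24, others -0.01 to 0.03). Replicate 3 did so for Rida (-1.14, others -1.36 to -1.33), Vcan (0.093, others 0.43 to 0.46), Vwf (-0.85, others -0.11 to -0.06) and Igfbp4 (0.039, others 0.38 to 0.43). Replicate 4 did so for Bmp4 (0.054, others -0.21 to -0.17) and Slc1a2 (-0.41, others -0.64 to -0.61).

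The real assignment of mutant and control within the pairs was compared with the other ways to swap them, 7 splits in all that can be fitted with a dye term. For genes, 1 of the 7 splits, the real one, gave as many calls (186), and the highest other count was 0. In each other split a genotype difference falls wholly or partly into the residual. Genes that differ by genotype are then hard to call, so 0 is not a count for noise alone. For gene lists, 2 of the 7 splits gave as many calls as the real 13, and the highest other count was 17, in a split with the mutant's dye unbalanced. Every other split gave list calls too, and the other splits with balanced dyes gave 8 and 4. In splits with unbalanced dyes the contrast still holds part of the genotype difference, so their calls partly repeat it. In the other balanced splits genotype cancels out of the contrast, and camera at the preset correlation called lists there too. With 7 splits no share under 0.05 can be reached for either.

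Mature astroglial genes moved both ways. Fewer astroglial cells would lower the members together, and 2 members were higher past the threshold in all 4 pairs (Aldh1l1 and Slc14a1). These 2 genes are part of the pattern itself, so the outcome of this test was fixed when it was chosen. It restates the pattern, and no conclusion on fewer cells is drawn from it. A general delay of astroglial maturation would leave no mature gene higher and no immature gene lower. The test of it counted the same 2 genes and was fixed in the same way, so a delay stays open. No immature gene was lower past the threshold. One probe standing for each gene is argued against as the whole cause, because further probes of Slc14a1 (1.09) and Aqp4 (-0.52 and -0.53) passed on both sides of 0. Further probes had the direction of the main probe for 100% of the 7 called astroglial genes, of 22, that have them. One probe standing for some of the genes cannot be told apart: 18 of the 22 had no further probe that passed, and some further probes were near 0 (Gria4, -0.07). Of these 18, 15 had no further tested probe, Aldh1l1 and Cldn10 among them. A partial loss of cells, or a partial delay beside another response to the genotype, stays open and was not tested.

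In pair 1, some genes known from neutrophils or bone had high ratios: S100a8 (2.70), S100a9 (2.80), Ltf (2.20), Camp (2.24), Bglap (3.00) and Col1a1 (2.06). The other pairs lay between -0.64 and 0.62; these genes were named after their values were seen. Lists of 18 further marrow genes and 14 further bone genes were then written before they were looked at. A response to the genotype shared by the pairs is argued against, because the highest marrow median in the other 3 pairs was 0.035, against 0.31 in pair 1, where Mpo stood at 1.55, Retnlg at 1.34 and Ngp at 1.30. Bone and marrow left on the mutant cerebellum of pair 1 may account for it but cannot be told apart from other sources: the bone median in pair 1 was 0.035 (0.077 in pair 2), so bone genes as a group were not higher there, and it lay under the bound of 0.3 set beforehand. That bound was set aside after it had been met. The reason was that 9 of the 14 bone genes were above background in all 8 channels, where a small share of bone would be hidden. Of the other bone genes, Acp5 (1.09) and Mmp13 (1.02) were higher, but Runx2 (0.12), Ifitm5 (0.01) and Ibsp (-0.03) lay near 0. Runx2 and Ibsp were not above background in the mutant channel of pair 1. Without replicate 1 the counts of called genes were 44 and 13.

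There were 10 genes with large ratios of opposite sign in different pairs: Adat2, Ankrd29, Dusp16, Egfbp2, Klk1b24, Klk1b3, Klk1b8, Nrgn, Xlr3c and Xlr4b, chosen by a spread over 1.5 in both directions. Klk1b24 ran from -3.99 to 4.49. The kallikrein genes (Egfbp2 among them) and the Xlr genes are paralogs whose probes are not independent. A strain or litter variant stays open: 60% of the genes took 2 levels over the 8 channels, against 18% of 200 genes matched on brightness, but choosing genes with ratios of both signs favours 2 levels by itself, and the matched genes were not chosen so. What was set down beforehand for a variant was met, and was set aside afterwards for that reason. The labels give a mixed strain background. RNA of another tissue in one channel could not be told apart, since the largest gap parted 1 channel from the others for 40% of the genes, against 38% of matched genes. None of the 10 genes was called.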

How the results depend on the processing

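The order of outlier flags and normexp was chosen after the data had been seen, and the earlier order was added as an alternative then; the other alternatives were planned. All 186 called genes kept their direction in each alternative in which they were tested (176 of 176 with the stricter filter). Each had 1 sign in all pairs, so settings that only left out or reweighted pairs could not reverse it on the same probe. The count bears on direction only where ratios were recomputed, as with the background correction, the processed signals or the mean over probes. Flags after normexp gave 50 genes higher and 32 lower, and 79 of the 186 were still called. That order puts all flagged spots into the normexp fit, whose mean in Cy3 for replicate 1 was then -730 in place of 8.62. The effect of the speck alone on the counts was not tested. Settings without normexp gave 99 and 78 (no background subtraction) and 88 and 53 (processed signals, and likewise the series matrix values). No replicate block, which ignores that the channels are paired, gave 95 and 67, and 141 of the 186 were still called. Leaving out each replicate in turn gave 44 to 215 genes higher and 13 to 127 lower, with fewer arrays and 1 residual degree of freedom. Without replicate 1 or 3, the residual came from replicates 2 and 4, each with an array weight of 0.706. Without replicate 2 or 4, it came from replicates 1 and 3, each with a weight of 1.42 (higher for less variable arrays). A low count thus need not mean that the omitted pair carried the calls. Why the counts differed was not tested beyond this. The 1.5-fold threshold gave 86 and 59. The dye effect passed for 0 genes, and for 0 to 1 when 1 replicate was left out (1 without replicate 2). Dicer1 stood at -0.013 with the mean of its probes, and between -0.054 and 0.13 with 1 replicate left out, and was called in none of the alternatives. Lists called higher and lower numbered 0 and 0 with an estimated correlation, and 1 and 2 by fry, which put another question. The choroid plexus list reversed without replicate 4 (-0.17) and stood at 0.39 without replicate 2; the cause was not tested. Of 39 named genes that were called, 15 kept the call in each alternative, and of 699 values 57 missed the threshold without a change of direction. Of 13 called lists none kept the call in each alternative, and 35 of 260 values missed the threshold. Of 17 lists not called, 4 stayed so with the same direction of the test in each alternative. Of their 340 values in all, 25 changed direction without passing and 16 passed in the direction of the value reported. Only 1, the choroid plexus list without replicate 4, passed in the other direction. The microRNA seed test and its 8-base alternative were not run. With the processed signals Cxcl10 stood at 4.66, Dhrs2 at -2.76 and Eda2r at 2.60, against 0.71 for Eda2r in the main fit. The control channel of Eda2r was above background on 0 of 4 arrays. The cause of these differences was not tested.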

Other observations

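The test on symbol stems and the test on cell types were chosen after the result was seen; the test on position near Dicer1 was set down before. Of 10 tested genes of the S100a family, small calcium-binding proteins, 4 fell in mutant cerebellum and the other 6 did not pass. The 4 were S100a6 (-1.03 ± 0.21, SD, n = 4 pairs), S100a10 (-0.99 ± 0.15), S100a1 (-0.65 ± 0.12) and S100a13 (-0.61 ± 0.17). Of the others, S100a16 stood at -0.41 ± 0.18 (adjusted p = 0.0632 in limma), S100a11 at -0.18 ± 0.23, S100a4 at -0.08 ± 0.23 and S100a3 at 0.07 ± 0.07. S100a8 and S100a9, which neutrophils carry, stood at 0.40 ± 1.55 and 0.40 ± 1.60, with high values in pair 1 alone. Chance gathering of one gene family was tested over 390 symbol stems with at least 5 tested genes, in both directions (780 tests). The lowest adjusted Fisher exact p was 8.66e-05, for lower genes with the stem S100a. This definition of a stem replaced a first one that split the S100a names, under which the lowest adjusted Fisher exact p was 0.246 over 441 stems. The S100a genes had been seen among the calls by then, so the test was fitted to the genes that prompted it, and chance stays open.

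Of 104 genes of 6 astroglial lists 22 were called (21.2%), 10 of them higher, against 0 of 175 genes of 11 lists of other cell types. An unadjusted p under 0.05 in limma was reached by 50 of the 104 and by 14 of the 175. The 2-sided Fisher exact p for the called shares was 7.97e-11, but the split into astroglial and other lists was tested because these calls had been seen, and genes of a list are not independent, so an even spread of the change over cell types stays open. Of the 186 called genes, 25 were in any list and 161 in none.

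Variants linked to the floxed Dicer1 allele were considered for the called genes. None of 181 tested genes within 10 Mb of Dicer1 on chromosome 12 was called, against 186 of 17755 elsewhere (1.05%), with a 2-sided Fisher exact p of 0.270. A share no higher than elsewhere had been set down beforehand as evidence against it; this was met, and set aside afterwards, because these shares were not told apart by the test, and how far the linked segment reaches in this mixed background is unknown, so such variants stay open for called genes farther away. In the window, 6 genes had the same sign in all pairs with an unadjusted p under 0.01 in limma but did not pass adjustment.

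Ratios of single pairs correlated across genes at 0.0056 to 0.427 between pairs, where genes are not independent replicates.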
